A study of Mus musculus with 10 samples.

How the data were processed

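RNA of Foxp3-expressing (GFP-positive) CD4 T cells from spleen and lymph nodes was hybridised to 10 Affymetrix arrays in 4 groups: TCR-negative and TCR-positive CD44hi cells (2 arrays each) and TCR-negative and TCR-positive CD62Lhi cells (3 arrays each). Per the labels, T cells were enriched by positive selection and sorted on CD4, GFP, TCR beta, CD44 and CD62L, and RNA was extracted with Trizol. The values are log2 intensities made by the authors with RMA, per the submitters' processing notes, which give no version. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of each probe set, so differences of low-intensity genes are compressed. Which arrays were normalized together is not given in the sources used here. Groups and replicate numbers were taken from the sample labels. Correlations between arrays of a group ran from 0.9954 to 0.9978, and no 2 arrays held the same values throughout. For arrays, the number of replicates limits the precision.

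The table held 22690 probe sets, 64 of them array controls. In the platform annotation 20393 probe sets had 1 gene symbol, 691 had several and 1606 had none; 20364 of those with 1 symbol were matched to the reference by gene identifier and 0 symbols changed. Probe sets with 1 symbol gave 12394 genes, 4958 of them with more than 1 probe set, for which the one with the highest mean over all arrays was used. Probe sets of Ccnd2 and Ola1 were called in opposite directions in CD44hi cells. Probe sets with several symbols or none were left out of the gene tests and tested separately.

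All 10 arrays were fitted in limma (version 3.58.1, R 4.3.3) with a mean for each group and an empirical Bayes variance shared over the groups. The contrasts were TCR-negative against TCR-positive in CD44hi and in CD62Lhi cells, the difference of these (the interaction), and CD44hi against CD62Lhi with and without a TCR. P-values were two-sided and adjusted by Benjamini-Hochberg within a contrast, and a gene was called at an adjusted p under 0.05. The design, the gene lists, the rule for named genes and all alternatives except the fit with 2 arrays in every group were fixed before the data were examined. Named genes were the 10 largest rises and 10 largest falls among called genes of each contrast (the text may stop at 5 for the last 3 contrasts), up to 4 members of each list with the smallest p, and Foxp3, Il2ra, Ctla4, Ikzf2, Irf4, Egr2, Nr4a1, Ebi3, Il10, Cd5, Cd69, Cd44, Ccr7 and Mki67; predicted genes were skipped among the largest changes. Cd69 was not analysed here, and some other genes of the rule and the lists are not reported here.

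There were 21 gene lists with 356 members, 304 of them measured: TCR complex and proximal signalling, TCR-induced immediate and early genes, Treg signature, Treg effector molecules, chemokine receptors and trafficking, naive and quiescence genes, cell cycle, cholesterol synthesis and uptake, glycolysis, TNF receptor and NF-kB targets, interleukin-2 and STAT5 targets, interferon response, T helper lineage genes, survival and apoptosis, markers of B and antigen-presenting cells, of myeloid and dendritic cells, of CD8 and NK cells, of gamma-delta T and NKT cells, of erythroid cells and platelets, heat shock and dissociation stress, and sex-linked genes. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, with an adjustment over the lists of a contrast, and again with an estimated correlation. Limma's fry, which tests a list against no change and not against other genes, was run beside it with the same adjustment. List calls are those of camera unless fry is named. With the estimated correlation the calls of the early, signature, effector, cell cycle and T helper lists in CD44hi cells and of the early, signature and interferon lists in CD62Lhi cells held, and those of other lists in these 2 contrasts did not.

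Replicate numbers were taken to pair TCR-negative and TCR-positive arrays of a subset, from the data and not from the labels: deviations from the group means of arrays with the same number had correlations of 0.427, 0.26 and 0.417 in CD62Lhi cells. In CD44hi cells both pairs had 0.185, which is a single observation, since the deviations of 2 arrays from their mean mirror each other. There the pairing is not established. The main fit has group means only and does not use the pairing, so its p-values ignore it. Where a fit with this number as a block changes the call of a list or a count of genes or list members given in the text by more than 1.5 times, its value stands beside the result, as it does for some single genes. Overlaps of calls were compared with the product of the list lengths over the genes tested and with Fisher's exact test. Log2 fold changes of contrasts that share arrays were compared with 100 simulations without an effect.

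The fit was tested on simulated arrays before use. In CD44hi cells 56% of 50 genes changed by 0.5 on the log2 scale were recovered and 96% of those changed by 1, with 8 false calls among 184. In CD62Lhi cells 88% and 98% were recovered, with 14 false calls among 207. Alternatives were a fit of the 2 groups alone, a mean-variance trend, robust variance, array weights, dim probe sets left out (below percentile 40, a log2 value of 5.175), the mean of all probe sets of a gene, a shift of the arrays to one median, cyclic loess, quantile normalization, replicate blocks, 2 arrays in every group, and each array left out in turn. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.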

Results

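Regulatory T (Treg) cells, the Foxp3-expressing CD4 T cells that restrain immune responses, were sorted from the spleen and lymph nodes of tamoxifen-treated mice in which a Cre recombinase expressed from the Foxp3 locus can delete the constant region of the T cell receptor (TCR) alpha chain. TCR-negative and TCR-positive cells were separated by surface TCR beta. Within each, activated cells (CD44 high, CD62L low, called CD44hi here) and resting cells (CD44 low, CD62L high, called CD62Lhi) were collected. RNA was measured on 10 Affymetrix arrays: 2 of TCR-negative CD44hi, 2 of TCR-positive CD44hi, 3 of TCR-negative CD62Lhi and 3 of TCR-positive CD62Lhi cells. The number of arrays limits the precision of every value. The labels do not say that the arrays came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

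TCR alpha transcripts were lower in the TCR-negative cells of both subsets. The probe set with the largest difference, annotated to the alpha variable gene Trav9d-3, had a mean log2 intensity of 12.45 ± 0.07 (SD, n = 2) in TCR-positive and 10.57 ± 0.05 (SD, n = 2) in TCR-negative CD44hi cells, a log2 fold change of -1.89 (SE 0.09, limma adjusted p = 1.46e-06). In CD62Lhi cells it was 12.07 ± 0.03 (SD, n = 3) and 10.17 ± 0.07 (SD, n = 3), a log2 fold change of -1.90 (SE 0.07, limma adjusted p = 4.79e-07). The other 4 probe sets with this symbol had log2 fold changes between -0.34 and -0.70. A TCR beta probe set annotated to Trbv1 was at 13.35 and 13.31 in TCR-positive and TCR-negative CD44hi cells. Where the alpha probes lie relative to the deleted constant region is not known here, so these values do not by themselves check the deletion.

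The first comparison asked what changed in activated Treg cells after loss of the TCR. Genes induced by TCR signalling, suppressive molecules of Treg cells and cell cycle genes were lower in TCR-negative CD44hi cells (n = 2 and 2). The log2 fold change was -3.48 (SE 0.24) for Egr2, a transcription factor gene switched on by TCR signals, -3.32 (SE 0.15) for Il1r2, a decoy receptor for interleukin-1, and -2.92 (SE 0.14) for Penk, which encodes proenkephalin. It was -2.53 (SE 0.11) for Ebi3, a subunit of interleukin-35, and -2.44 (SE 0.21) for Il10, the gene of an anti-inflammatory cytokine. Klf2, a transcription factor of quiescent and recirculating T cells, rose by 1.22 (SE 0.12), the chemokine receptor gene Cxcr4 by 1.14 (SE 0.14) and the interferon-gamma receptor gene Ifngr1 by 1.03 (SE 0.09).

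Il10 was at 3.35 in TCR-negative CD44hi cells and Birc5, Cdc6, Ccne2 and Il21 were at 3.77, 3.39, 3.34 and 3.26 there, below the lower quartile of every array (4.10 or more), where background limits how low a gene can read. Ube2c and Cd68 were also below it there, so the falls given for these 7 genes are best read as lower bounds. The other large falls in CD44hi cells were in Birc5 (-3.18), Stmn1 (-2.96), Ccnb2 (-2.63), Egr1 (-2.49) and Ube2c (-2.37). Among genes with a single symbol, the other large rises were in Qpct (1.34), L1cam (0.90), Pde2a (0.90), Ptprd (1.02), Trp63 (0.92), Tle5 (0.90) and Frk (0.90). The calls of Ptprd, Trp63, Tle5 and Frk were each lost without TCR-negative CD44hi replicate 2 or without TCR-positive CD44hi replicate 1. Those of Ptprd, Trp63 and Frk were also lost without TCR-negative CD44hi replicate 1, those of Ptprd and Frk without TCR-positive CD44hi replicate 2, those of Ptprd and Trp63 with the mean of all probe sets of a gene, and that of Frk without replicate 2 of either CD62Lhi group, after cyclic loess and after quantile normalization. Ptprd, Trp63 and Frk had mean log2 intensities of 4.19, 3.13 and 3.81 in TCR-positive CD44hi cells, in the dim range where TCR-negative arrays read higher (median log2 fold change 0.121 over the dimmest 4132 genes).

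Of 20 measured immediate and early genes of TCR signalling, 10 fell and 0 rose in CD44hi cells (10 adjusted over the list alone), with Irf4 at -1.95 (SE 0.16), Nr4a1 at -2.08 (SE 0.26), Nfatc1 at -1.37 (SE 0.09) and Irf8 at -1.23 (SE 0.10). The list fell (camera adjusted p = 6.93e-07; adjusted p = 0.0421 with an estimated correlation). Of 18 Treg effector molecules, 8 fell and 1 rose (9 and 1 adjusted over the list alone), including Pdcd1, an inhibitory receptor gene, at -1.73 (camera adjusted p = 4.09e-06; adjusted p = 0.0417 with an estimated correlation). Of 20 Treg signature genes, 6 fell and 1 rose (8 and 2 adjusted over the list alone), with the inhibitory receptor gene Ctla4 at -1.10 (SE 0.11), Tnfrsf4 at -0.88 and Plagl1 at -1.49 (camera adjusted p = 0.000918; adjusted p = 0.0435 with an estimated correlation). The interleukin-2 receptor gene Il2ra had a log2 fold change of 0.26 (SE 0.10, limma adjusted p = 0.107). The Foxp3 probe set was at 3.30 in TCR-positive CD44hi cells, and over the arrays its mean was at percentile 12.7 of all probe sets, so it says nothing about Foxp3.

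Cell cycle genes fell together in CD44hi cells: 23 of 29 were lower and 0 higher (24 adjusted over the list alone), with Mki67, a marker of dividing cells, at -1.88 (SE 0.20), Cdc6 at -2.08 and Ccne2 at -1.44 (camera adjusted p = 2.64e-22; adjusted p = 0.0417 with an estimated correlation). Of 14 TNF receptor and NF-kB target genes, 7 fell (7 adjusted over the list alone), among them Cd83 at -2.03 and Tnfrsf9 at -1.46 (camera adjusted p = 3.45e-05; adjusted p = 0.0726 with an estimated correlation). Of 17 T helper lineage genes, 6 fell and 1 rose (7 and 2 adjusted over the list alone, and 7 and 2 with the replicate block within subsets), with Myb at -2.35, Bcl6 at -1.64, Il21 at -1.92 and Il4 at -1.76 (camera adjusted p = 0.00192; adjusted p = 0.0435 with an estimated correlation). The call was lost without dim probe sets (adjusted p = 0.355, with 0.00011 as the lowest of the alternatives).

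Of 17 naive and quiescence genes, 6 rose and 2 fell in CD44hi cells (7 and 2 adjusted over the list alone), with Igfbp4 at 0.77 and Txnip at 0.71 and Id3, an inhibitor of E-protein transcription factors, at -0.82 (camera adjusted p = 0.0140; adjusted p = 0.104 with an estimated correlation; 0.0554 in a fit of these 2 groups alone, the highest of its alternatives, which began at 0.000983). Of 15 interferon response genes, 7 rose and 0 fell (8 and 1 adjusted over the list alone, and 8 and 1 with the replicate block within subsets), with Ifit1 at 0.86 and Igtp at 0.52 (camera adjusted p = 0.00168; adjusted p = 0.0687 with an estimated correlation). Of 11 interleukin-2 and STAT5 targets, 6 rose and 2 fell (7 and 3 adjusted over the list alone), with Socs3 at 0.55 and Gadd45b at -0.75. Fry called this list (fry adjusted p = 0.0041) and camera did not (camera adjusted p = 0.124). The list was called without dim probe sets (adjusted p = 0.0363) and after cyclic loess (0.0308), over a range of 0.0308 to 0.224. The calls of Igtp and Socs3 were lost without TCR-positive CD44hi replicate 2. Chemokine receptor and trafficking genes went both ways, with 3 of 20 higher and 3 lower, among them Ccr8 at -1.12 and Selplg at 0.68 (camera adjusted p = 0.184). Members of the TCR complex and proximal signalling list (2 of 16 higher, 2 lower, camera adjusted p = 0.656), of cholesterol synthesis (1 of 15 higher, 0 lower, camera adjusted p = 0.816), glycolysis (2 of 15 lower, camera adjusted p = 0.584) and survival genes (2 of 11 lower, camera adjusted p = 0.167) gave no camera call. Fry called the survival list lower (fry adjusted p = 0.0457, median log2 fold change -0.13). With the replicate block within subsets 5 chemokine receptor and trafficking genes, 4 glycolysis genes and 1 cholesterol gene were lower.

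Camera called no list of markers of other cell types in CD44hi cells. Fry called the gamma-delta and NKT list (adjusted p = 0.0477) and the erythroid and platelet list (adjusted p = 0.0108). Their median log2 fold changes were 0.21 and 0.20. Fry tests against no change, and the dimmest 4132 genes had a median log2 fold change of 0.121 in this contrast. Whether that shift of dim genes accounts for these 2 calls was not tested. Among 13 B cell and antigen-presenting cell markers, Cd22 (-1.05) and Cd74, the invariant chain of MHC class II (-0.73), fell and Ms4a1 rose by 0.72 (camera adjusted p = 0.932). H2-Aa, H2-Ab1, H2-Eb1 and Cd79a were at 4.80, 4.47, 5.83 and 4.11 in TCR-positive CD44hi arrays, below the median of all probe sets of 6.05. Among 16 myeloid markers, Lyz1 (-0.95) and Cd68 (-0.65) fell and Csf1r rose by 0.39 (camera adjusted p = 0.470). Among 10 CD8 and NK cell markers, Nkg7 fell by 1.29 and Cd8a rose by 0.39 (camera adjusted p = 0.619). Zbtb16 rose by 0.38 among 3 gamma-delta and NKT markers (camera adjusted p = 0.167), and 0 of 6 erythroid markers were called (camera adjusted p = 0.134). The calls of Cd74, Ms4a1, Lyz1, Cd68, Csf1r, Cd8a and Zbtb16 were each lost without TCR-negative CD44hi replicate 1 or without TCR-positive CD44hi replicate 2, and each also without at least another CD44hi array. Of 14 heat shock and dissociation stress genes, Dnajb1 rose by 0.62 and no other was called (camera adjusted p = 0.266); that call was lost without TCR-positive CD44hi replicate 1. Of 4 sex-linked genes, 0 were called (camera adjusted p = 0.0691, and 0.0356 with the replicate block within subsets, over a range of 0.0251 to 0.174). Without TCR-negative CD44hi replicate 1 or TCR-positive CD62Lhi replicate 1 the list was also called. With the replicate block within subsets Ppbp, an erythroid and platelet marker, was called higher and the sex-linked genes Eif2s3y and Uty lower (adjusted p = 0.0435, 0.0149 and 0.0179, over ranges of 0.0378 to 0.345, 0.0126 to 0.335 and 0.0141 to 0.310). In that fit 2 B cell and antigen-presenting cell markers were higher and 3 lower, 2 myeloid markers were higher and 2 lower, and 2 CD8 and NK cell markers were higher and 1 lower. In the main fit, fry called the sex-linked list (fry adjusted p = 0.0442). That list pools Xist with genes of the Y chromosome, so its direction alone cannot test a difference in sex. Its Y chromosome genes Eif2s3y, Uty and Kdm5d had log2 fold changes of -0.405, -0.428 and -0.322 in a fit with the replicate number as a block over all samples. None of them was called in the main fit. A difference in sex between the samples was not tested and stays open.

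In all, 1194 of 12394 genes were called in CD44hi cells, 395 higher and 799 lower, and 5 of the higher and 130 of the lower ones changed at least 2-fold. With replicate numbers as a block within each subset, 2255 genes were called. Without TCR-negative CD44hi replicate 1 or 2 the count was 631 or 412, and without TCR-positive CD44hi replicate 1 or 2 it was 407 or 443. The split between higher and lower calls moved with the scaling, to 552 and 708 after quantile normalization and to 728 and 657 when the arrays were shifted to one median.

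**Figure D1:**
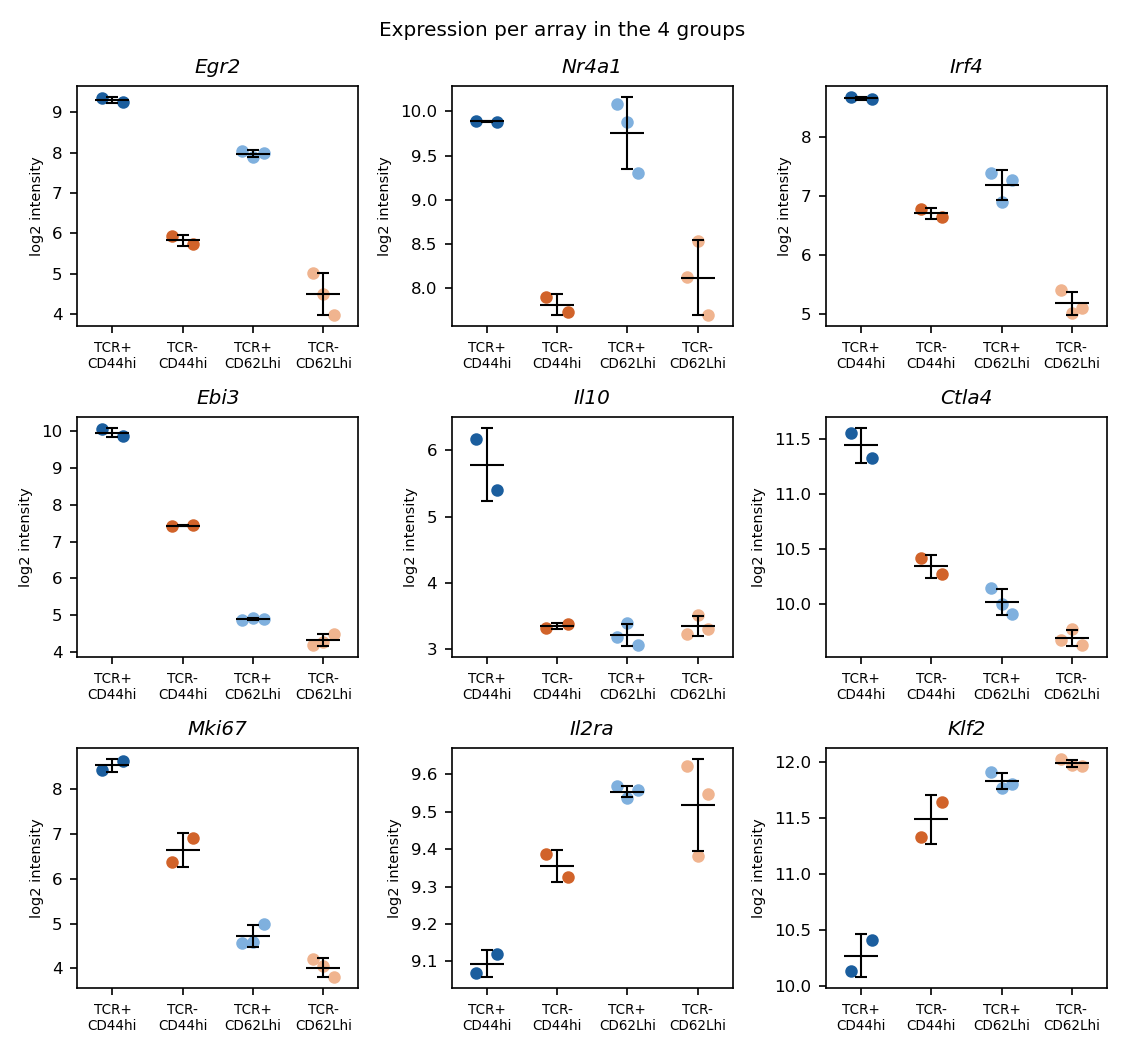
Log2 intensity (y axis) of 9 genes on each array (dots) in the 4 groups, with the group mean and SD (bars, n = 2 for CD44hi and n = 3 for CD62Lhi groups). Egr2, Nr4a1 and Irf4 sit lower in TCR-negative cells of both subsets, while Il10 is at 5.79 in TCR-positive CD44hi cells and near 3.35 in TCR-negative ones.

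The second comparison asked the same of resting Treg cells. TCR-negative CD62Lhi cells (n = 3 and 3) had lower levels of TCR-induced transcription factors: the log2 fold change was -3.49 (SE 0.20) for Egr2, -2.37 (SE 0.19) for Egr1, -1.76 (SE 0.13) for Nab2 and -1.64 (SE 0.21) for Nr4a1. Irf4, a transcription factor gene of effector Treg cells, fell from a mean log2 intensity of 7.18 to 5.17 (SE of the difference 0.13). Other large falls were in Cd83, an activation marker (-2.10, SE 0.10), Plagl1 (-1.97, SE 0.14), the transcription factor gene Myb (-1.96, SE 0.11), the costimulatory receptor gene Tnfrsf9 (-1.63, SE 0.13) and Slc22a2, an organic cation transporter gene (-1.39, SE 0.17). Tec, which encodes a kinase of antigen receptor signalling, rose by 1.24 (SE 0.08), Myo6 by 0.85 (SE 0.11) and the kinase gene Pim1 by 0.69 (SE 0.10). The 7 other rises, Prdm1 (0.60), Socs3 (0.54), Gramd3 (0.50), Irgm2 (0.44), Ighm (0.44), Irgm1 (0.41) and Spsb1 (0.40), each lost the call without TCR-negative CD62Lhi replicate 1.

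Of 20 immediate and early genes, 6 fell in CD62Lhi cells (10 adjusted over the list alone; camera adjusted p = 8.84e-17; adjusted p = 0.00578 with an estimated correlation). Of 20 Treg signature genes, 3 fell (11 adjusted over the list alone, and 6 with the replicate block within subsets), with Tnfrsf4 at -0.88 (camera adjusted p = 1.73e-12; adjusted p = 0.00522 with an estimated correlation). Of 14 TNF receptor and NF-kB targets, 2 fell (3 adjusted over the list alone; camera adjusted p = 2.80e-07; adjusted p = 0.0587 with an estimated correlation). Interferon response genes rose as a list although 0 of 15 were called singly (8 adjusted over the list alone, and 1, Gbp3, with the replicate block within subsets), with a median log2 fold change of 0.24 (camera adjusted p = 6.73e-08; adjusted p = 0.0143 with an estimated correlation). Cell cycle genes had a median of -0.16, with 0 of 29 called (4 lower adjusted over the list alone, and 1, Ccnb2, with the replicate block within subsets), and Mki67 was at -0.70 (limma adjusted p = 0.111). The list call (camera adjusted p = 3.85e-06) was lost with an estimated correlation (adjusted p = 0.240). Of 18 Treg effector molecules, 4 fell and 1 rose, with Pdcd1 at -0.81 and Prdm1 at 0.60. The list call (camera adjusted p = 0.0483) was lost with an estimated correlation (adjusted p = 0.240) and with the replicate block within subsets (adjusted p = 0.0670, over a range of 0.00388 to 0.171). It was also lost without TCR-negative CD62Lhi replicate 1 or TCR-positive CD62Lhi replicate 1 or 3. Among markers of other cells, Cd74 fell by 0.95 (SE 0.13) while H2-Aa, H2-Ab1, H2-Eb1 and Cd79a were at 4.65, 4.53, 5.63 and 4.33 in TCR-positive CD62Lhi arrays, below the median of all probe sets of 5.97. The CD8 and NK marker list was lower with 0 of 10 called (camera adjusted p = 0.0370; adjusted p = 0.299 with an estimated correlation), and its call was lost without TCR-negative CD62Lhi replicate 1 or 2 or TCR-positive CD62Lhi replicate 1 or 3. Il10, Ctla4 and Il2ra had log2 fold changes of 0.14, -0.33 and -0.04 and were not called, and Ikzf2 was at -0.57 (limma adjusted p = 0.267, and 0.0487 with the replicate block within subsets, over a range of 0.0487 to 0.596).

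In all, 56 genes were called in CD62Lhi cells, 10 higher and 46 lower. With replicate numbers as a block within each subset, 114 genes were called. Without TCR-positive CD62Lhi replicate 3 the count was 36.

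**Figure D2:**
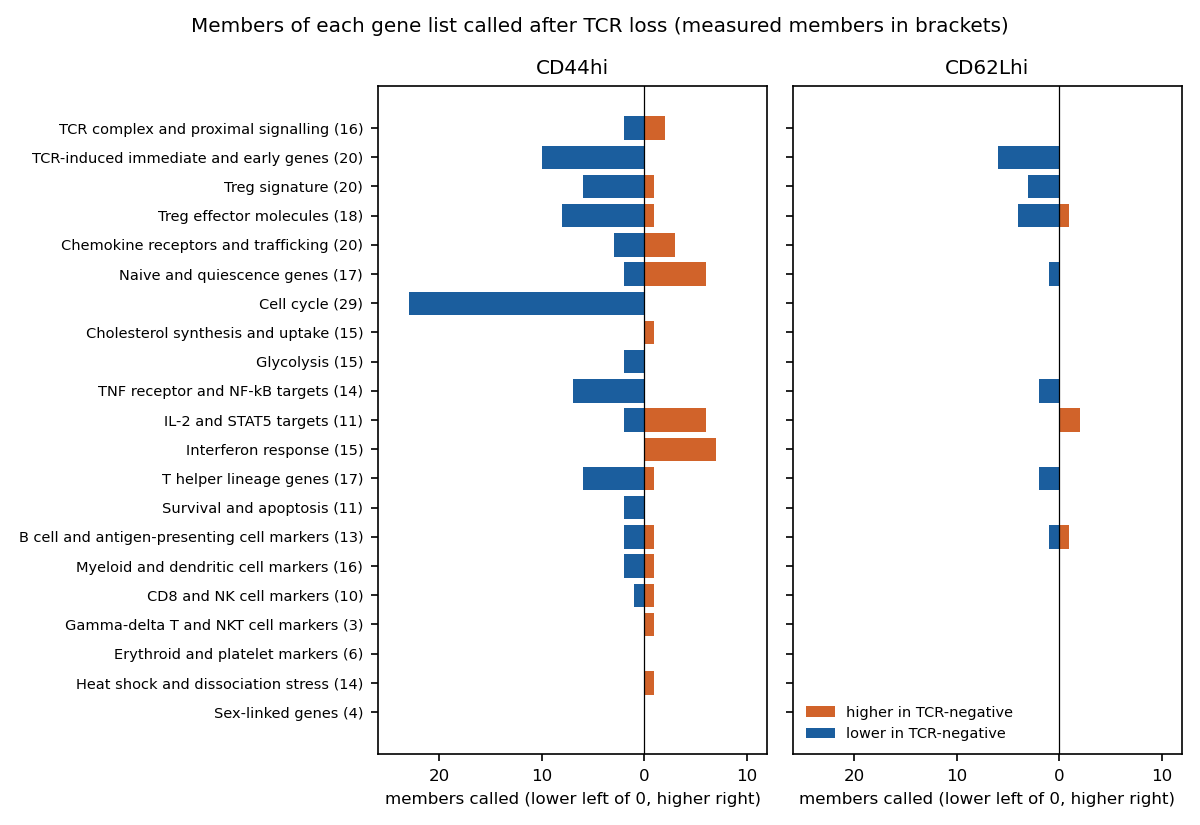
Number of members of each gene list called after TCR loss in CD44hi (left) and CD62Lhi (right) cells, lower to the left of 0 and higher to the right, with measured members in brackets. In CD44hi cells 23 of 29 cell cycle genes were lower, and in CD62Lhi cells 0 were called in this fit.

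The third comparison asked whether the change after TCR loss differed between activated and resting cells. For several genes the fall in CD44hi cells exceeded the change in CD62Lhi cells: the interaction log2 difference was -3.07 (SE 0.31) for Birc5, -2.93 (SE 0.19) for Il1r2, -2.57 (SE 0.27) for Il10, -2.33 (SE 0.17) for Penk, -2.21 (SE 0.16) for Ccnb2 and -1.96 (SE 0.14) for Ebi3. Il10 and Birc5 were at 3.22 and 3.81 in TCR-positive CD62Lhi cells, also below the lower quartile, which leaves little room to measure a fall there. Penk, Ccnb2 and Mki67 ended below it in TCR-negative CD62Lhi cells, at 3.54, 3.86 and 4.02, so their falls there are best read as lower bounds and the size of their differences as upper bounds. Of the 199 genes with a negative difference, 74 were below a log2 intensity of 5.175 in TCR-positive CD62Lhi cells. Ebi3 was among them, at 4.855 to 4.917, and was at 4.176 to 4.497 in TCR-negative CD62Lhi cells. Its fall there may also be cut short by background, which would make its difference too large. The difference was positive for Klf2 (1.06, SE 0.16), Qpct (1.18, SE 0.18) and L1cam (1.05, SE 0.19), whose log2 fold changes in CD62Lhi cells, 0.16, 0.15 and -0.14, were not called. For Egr2, Irf4 and Nr4a1 the interaction was 0.01 (SE 0.31), 0.05 (SE 0.21) and -0.44 (SE 0.34), and none of these was called. Egr2 was at 5.012, 4.483 and 3.964 and Irf4 at 5.403, 5.017 and 5.106 on the TCR-negative CD62Lhi arrays. Background may cut their falls short there, so these values do not establish equal falls of Egr2 and Irf4 in the subsets. Of the 20 early genes, 3 were called, all negative: Nfatc1 (-1.18, SE 0.12), Rel (-1.17, SE 0.20) and Irf8 (-0.81, SE 0.13). With the replicate block within subsets 4 were lower and 2 higher. Camera did not call the list (camera adjusted p = 0.685). Optc (1.17) and Adam34 (1.11) also differed, at mean log2 intensities of 4.44 and 3.06 in TCR-positive CD44hi cells, in the dim range.

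The interaction of Ctla4 was -0.77 and that of Mki67 -1.18. Both calls, and those of L1cam and Adam34, were lost without TCR-positive CD44hi replicate 1, and the calls of Ctla4 and Mki67 also without TCR-negative CD44hi replicate 1 or replicate 2 of either CD62Lhi group, among others. Of 29 cell cycle genes, 10 differed (17 adjusted over the list alone; camera adjusted p = 1.14e-15; adjusted p = 0.0957 with an estimated correlation). So did 6 of 18 Treg effector molecules (7 adjusted over the list alone, and 7 lower and 2 higher with the replicate block within subsets; camera adjusted p = 5.11e-05; adjusted p = 0.0933 with an estimated correlation) and 3 of 17 naive and quiescence genes (5 adjusted over the list alone; camera adjusted p = 0.00676; adjusted p = 0.111 with an estimated correlation). The sex-linked list, whose direction cannot test a difference in sex, was not called (camera adjusted p = 0.0549). It was called with the replicate block within subsets (adjusted p = 0.0436, over a range of 0.0258 to 0.196), with array weights, with each of the 3 other scalings and without TCR-negative CD44hi replicate 1, TCR-positive CD44hi replicate 2, TCR-negative CD62Lhi replicate 1 or TCR-positive CD62Lhi replicate 1 or 3. In all, 246 genes differed, 47 with a positive and 199 with a negative difference. With replicate numbers as a block within each subset, 1046 genes differed. The count was 120 or 102 without TCR-negative CD44hi replicate 1 or 2, 110 or 98 without TCR-positive CD44hi replicate 1 or 2, 154 or 145 without TCR-negative CD62Lhi replicate 1 or 2, and 534 or 149 without TCR-positive CD62Lhi replicate 1 or 2.

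Most genes that fell in resting cells also fell in activated cells: 41 of the 46 were lower in CD44hi cells too, against 2.97 for independent lists (one-sided Fisher's exact test p = 5.77e-44). Of the 10 that rose in resting cells, 5 were higher in CD44hi cells too, against 0.32 (one-sided Fisher's exact test p = 7.08e-06). Both contrasts use the same variance estimate of each gene, and genes are not independent. These Fisher p-values are therefore descriptive only. With the replicate block within subsets, 81 genes were called in one direction in both subsets against 46 without it. Across all genes, which are not independent replicates, the log2 fold changes of the 2 subsets had r = 0.212 and rho = -0.007.

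**Figure D3:**
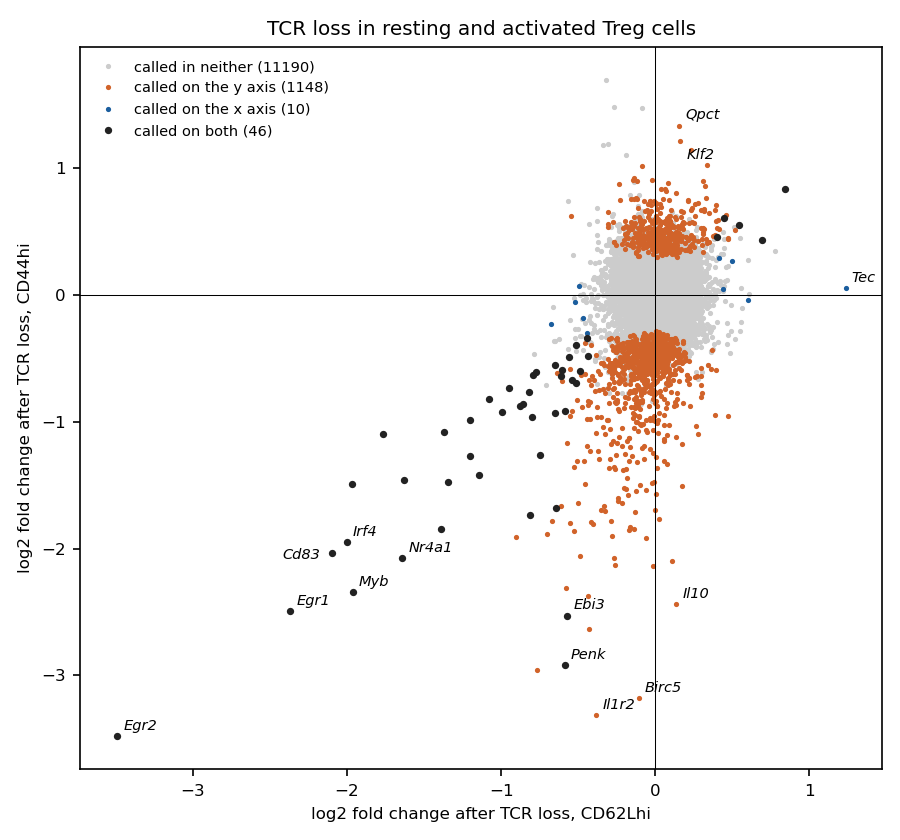
Log2 fold change after TCR loss in CD62Lhi (x axis) and CD44hi cells (y axis), 1 dot per gene, coloured by where the gene was called. Egr2, Egr1 and Irf4 lie far below 0 on both axes, while Il10 and Birc5 lie far below 0 on the y axis and near 0 on the x axis.

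The fourth comparison asked how much of the difference between activated and resting Treg cells was present without a TCR. In TCR-positive cells, the calcium-binding protein genes S100a4 and S100a6 were higher in CD44hi than in CD62Lhi cells by 6.28 (SE 0.18) and 5.74 (SE 0.25) on the log2 scale, and the chemokine receptor genes Cxcr6 and Cxcr3 by 5.99 (SE 0.14) and 5.23 (SE 0.13). In TCR-negative cells the differences were 6.79 (SE 0.18) for S100a4, 5.32 (SE 0.25) for S100a6, 5.04 (SE 0.14) for Cxcr6 and 5.48 (SE 0.13) for Cxcr3. Igfbp4, Myo6 and Cnn3 were lower in CD44hi cells, with log2 differences of -3.71, -3.96 and -3.81 with a TCR and -2.81, -3.97 and -4.11 without. Ebi3 and Penk were higher by 5.07 and 5.76 with a TCR and by 3.12 and 3.42 without. In CD62Lhi cells Cxcr6 was below the lower quartile with and without a TCR and Penk without, so these differences of Cxcr6 and that of Penk without a TCR are best read as lower bounds. Il10 was at 5.79 in TCR-positive CD44hi cells and between 3.22 and 3.35 in the other 3 groups, below the lower quartile, so its difference of 2.57 with a TCR is best read as a lower bound and no difference without a TCR can be read from it.

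Treg effector molecules were higher in CD44hi cells with a TCR (14 of 18, 1 lower; camera adjusted p = 8.71e-12; adjusted p = 0.00455 with an estimated correlation) and without (10 of 18, 1 lower; camera adjusted p = 4.57e-09; adjusted p = 0.00528 with an estimated correlation). Chemokine receptor and trafficking genes were higher with a TCR (13 of 20, 1 lower) and without (14 of 20, 0 lower), and naive and quiescence genes were lower (15 of 17, 1 higher, and 14 of 17, 2 higher). Of 29 cell cycle genes, 22 were higher with a TCR and 7 without, with 3 lower; without a TCR the list call (camera adjusted p = 0.0200) was lost with an estimated correlation (adjusted p = 0.471) and without dim probe sets. Ikzf2, a transcription factor gene, was higher in CD44hi cells by 1.83 with a TCR and 1.97 without, and Ccr7, a lymph node homing receptor gene, was lower (-1.35 and -1.49).

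With a TCR 3119 genes were called between the subsets, 1633 higher and 1486 lower in CD44hi cells, and without a TCR 2194, 1068 higher and 1126 lower. Which side was larger depended on the scaling. With a TCR the split was 1378 and 2727 when the arrays were shifted to one median, 1508 and 1680 after quantile normalization and 1776 and 1094 after cyclic loess. Without a TCR it was 964 and 1415, 1175 and 1264, and 1330 and 1027. Of the 3119 genes, 1375 (44.1%) were called in the same direction without a TCR. A line through 0 fitted to the log2 fold changes of all 3119 genes had a slope of 0.704, and the median ratio was 0.524. Fitted the other way, on the 2194 genes called without a TCR, the slope was 1.025. Choosing genes on one side inflates the differences on that side, so neither slope alone gives the share kept without a TCR. Without TCR-positive CD44hi replicate 1 or 2 the count with a TCR was 1719 or 1699, and without TCR-negative CD44hi replicate 2 the count without a TCR was 1288.

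Genes that fell after TCR loss in CD44hi cells were largely those higher in TCR-positive CD44hi than CD62Lhi cells, 573 of 799 against 105.27 for independent lists, and 231 of the 395 that rose were lower there, against 47.36. These comparisons are not independent, since they share the TCR-positive CD44hi arrays. The log2 fold changes had r = -0.621 against -0.548 in simulations with no effect and a covariance of -0.0955 against -0.0085. The simulated r follows from the numbers of arrays alone, so it does not measure how much the shared arrays contribute. The overlap was 804 genes against a mean of 0.03 in the same simulations, so shared noise without any real change does not give an overlap of this size. Part of the excess may still come from the shared arrays, since no gene had a real change in those simulations. The overlap of 804 genes was 452 or 335 without TCR-negative CD44hi replicate 1 or 2 and 326 or 333 without TCR-positive CD44hi replicate 1 or 2.

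**Figure D4:**
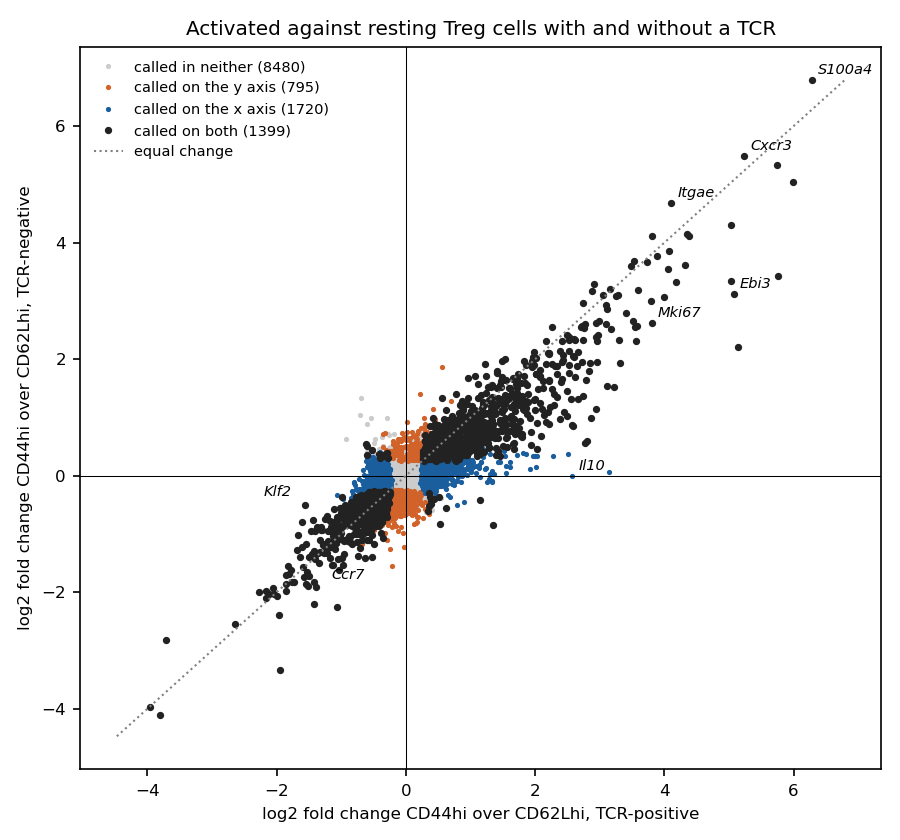
Log2 fold change of CD44hi over CD62Lhi cells with a TCR (x axis) and without (y axis), 1 dot per gene, with the line of equal change dotted. S100a4, Cxcr3 and Itgae lie near the line, while Ebi3, Mki67 and Il10 lie below it.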

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

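All tests of explanations in this part were chosen after the results were seen, except the count of splits of the CD62Lhi arrays.

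The change after TCR loss differed between CD44hi and CD62Lhi cells, by the test of the interaction, for 246 genes. Among them were Qpct (1.18), Optc (1.17), Adam34 (1.11), Klf2 (1.06) and L1cam (1.05), with a positive difference between the change in CD44hi and that in CD62Lhi cells, and Birc5 (-3.07), Il1r2 (-2.93), Il10 (-2.57), Penk (-2.33), Ccnb2 (-2.21), Ebi3 (-1.96), Mki67 (-1.18) and Ctla4 (-0.77), with a negative one. In TCR-positive CD62Lhi cells 74 of the 199 genes with a negative difference, Il10, Birc5 and Ebi3 among them, were below a log2 intensity of 5.175, which limits how far they can fall there. By the same test the median difference was -0.26 for Treg effector molecules, 0.26 for naive and quiescence genes, -0.54 for cell cycle genes and -0.18 for T helper lineage genes. With an estimated correlation the calls of the first 3 lists were lost (adjusted p = 0.0933, 0.111 and 0.0957). The call of the T helper list (camera adjusted p = 0.0146) was lost with the replicate block within subsets (adjusted p = 0.0531, over a range of 0.00149 to 0.566) and with an estimated correlation (adjusted p = 0.111). It was also lost without TCR-negative CD44hi replicate 1 or TCR-positive CD62Lhi replicate 1. Of 2246 probe sets without a single gene symbol, which enter no comparison of genes, 143 were called after TCR loss in CD44hi cells and 3 in CD62Lhi cells. Of the 143, 68 were higher and 75 lower. The largest of these rises were 1.64, 1.64 and 1.59, each above that of Qpct in the same cells. The probe sets at 1.64 had interaction differences of 1.48, above that of Qpct (1.18). The probe set at 1.59 also rose in CD62Lhi cells, by 0.63.

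More genes were called after TCR loss in CD44hi than in CD62Lhi cells, 1194 against 56. A wider distribution of values on the TCR-positive CD44hi arrays was tested with cyclic loess, after which 16.9 times as many genes were called in CD44hi cells, which argues against it as the whole cause, but only 40.2% of the 127 rises among the dimmest genes were still called, so many of those rises may come from it. The unequal number of arrays works the other way, since CD44hi cells had fewer: 56% of simulated changes of 0.5 were recovered there, against 88%. A difference between activated and resting cells in what the TCR maintains remains as a hypothesis that the design names and these tests leave open. For CD62Lhi cells, 1 of the 10 splits of the 6 arrays gave as many genes (56, with 2 as the highest of the others, and 0 among the other splits that part all 3 pairs); 10 splits are too few for a share under 0.05.

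The 10 largest falls in CD44hi cells could come from resting cells in the TCR-negative CD44hi gate. The falls would need a share of at least 84.3%, and 88.4% of the genes at least 8-fold higher in TCR-positive CD44hi than CD62Lhi cells (38 of 43) lay above the change this share predicts by over 2 SE, with a median of -0.75 against -2.24 predicted. That argues against resting cells as the whole cause. A smaller share, and a real fall of these genes in cells without a TCR, stay open.

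Egr2, Egr1, Nr4a1 and Irf4 fell in both subsets. A difference in handling stress would move the stress genes with them. The median of that list was 0.071 (SE 0.066) in CD44hi and -0.045 (SE 0.037) in CD62Lhi cells, which argues against handling stress as the whole cause. These 2 SEs come from resampling the 14 genes of the list, so they do not measure the spread between arrays. Without TCR-positive CD62Lhi replicate 3 the list was called lower in CD62Lhi cells (median -0.095, adjusted p = 0.00937, over a range of 0.00937 to 0.936) and its interaction was called (adjusted p = 0.0136, over a range of 0.0136 to 0.445). A signal from the antibody to TCR beta used in the sort, which binds TCR-positive cells alone, and a signal through the TCR in the animal cannot be told apart for these genes, because the groups differ in both by design. The 36 genes outside the early list that were called lower in both subsets do not decide it, since the time each needs to change was not measured. Loss of TCR signals stays open as the biological explanation.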

How the results depend on the processing

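The fit with 2 arrays in every group was chosen after seeing the data; all others were planned. No called named gene changed sign under any alternative run, and no list called in either fit changed its camera direction. The median of CD8 and NK markers in CD62Lhi cells went from -0.10 to 0.01 without dim probe sets and that of Treg effector molecules from -0.04 to 0.03 without TCR-positive CD62Lhi replicate 3, both with the call lost. Splits of calls moved with the scaling: when arrays were shifted to one median, from 395 higher and 799 lower to 728 and 657 in CD44hi cells and from 1633 and 1486 to 1378 and 2727 between the subsets with a TCR. In CD62Lhi cells 10 and 46 became 54 and 92 with a mean-variance trend, and for the interaction 47 and 199 became 389 and 657 with the replicate block within subsets. Between the subsets with a TCR the split also turned with quantile normalization (1508 and 1680) and array weights (1919 and 2119). Without a TCR, 1068 and 1126 turned to 1330 and 1027 after cyclic loess, 1015 and 994 in a fit of the 2 groups alone, 1116 and 1089 with the mean of all probe sets, 740 and 548 without TCR-negative CD44hi replicate 2, 995 and 966 without either TCR-positive CD44hi array, and 1001 and 820, and 835 and 818, without TCR-negative CD62Lhi replicates 1 and 2. Where no reason is given, the cause was not tested. For CD44hi cells 1194 genes became 2215 with array weights. For CD62Lhi cells 56 became 37 in a fit of the 2 groups alone and 29 with 2 arrays in every group (both use fewer arrays), 146 with a mean-variance trend and 99 without dim probe sets. The interaction count of 246 became 493 with the trend and 654 with array weights. The overlap of TCR-loss calls, 46, became 103 with the trend, 76 without dim probe sets and 28 with 2 arrays in every group. The slope of 0.704 became 0.754 without dim probe sets, 0.688 with arrays shifted to one median and 0.721 after quantile normalization, and the overlap of the CD44hi programme with TCR-loss calls, 804, became 1400 with array weights. With robust variance the 3 counts were 1179, 55 and 244.

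With the replicate number as a block within subsets the counts were 2255, 114 and 1046 for CD44hi, CD62Lhi and the interaction, and the overlap was 81. With the number as a block over all samples they were 1949, 98 and 862, and the overlap was 71; correlations across subsets of 0.201, 0.023, 0.147 and -0.092 do not establish a pairing there. Of named genes, the block within subsets gave 37 further calls and ended 1, and of lists it gave 2 and ended 2.

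Leaving out each array gave 407 to 1362 genes in CD44hi cells, 36 to 65 in CD62Lhi cells and 98 to 534 for the interaction, and 1699 to 3301 and 1288 to 2307 between the subsets with and without a TCR. The overlap of TCR-loss calls was 31 to 40, the slope 0.664 to 0.72, the genes called in both subset comparisons 1014 to 1402 and the programme overlap 326 to 849. Leaving out a CD44hi array leaves a group of 1, assumed to vary like the other groups. Counts that moved more than 1.5 times included 631 and 412 (TCR-negative CD44hi replicates 1 and 2) and 407 and 443 (TCR-positive CD44hi replicates 1 and 2) in CD44hi cells, and 36 without TCR-positive CD62Lhi replicate 3 in CD62Lhi cells. The interaction count was 120 and 102, and 110 and 98, without the same CD44hi arrays in that order, 154 and 145 without TCR-negative CD62Lhi replicates 1 and 2, and 534 and 149 without TCR-positive CD62Lhi replicates 1 and 2. Between the subsets it was 1719 and 1699 with a TCR, without TCR-positive CD44hi replicates 1 and 2, and 1288 without a TCR, without TCR-negative CD44hi replicate 2. The programme overlap was 452, 335, 326 and 333 without the CD44hi arrays in the first order. Over these fits, 278 values of named genes lost their call and 4633 kept their side of the threshold. Intensities near the floor, such as that of Foxp3, limit what can be measured.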

Other observations

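Other gene groups also differed between activated and resting Treg cells. Of 13 B cell and antigen-presenting cell markers, 4 were higher in CD44hi cells with a TCR, 1 lower, and 4 without a TCR, 0 lower: Cd22, an inhibitory receptor gene, by 2.53 (SE 0.14) and 1.77 (SE 0.14), Cd79b by 1.71 and 1.31, Cd74 by 1.17 and 1.39 and Ighm by 0.79 and 0.40 (camera adjusted p = 0.0797 with a TCR; 0.00196 without, and adjusted p = 0.0374 with an estimated correlation). With a TCR the median of the list was -0.03, and the list was called higher without dim probe sets (adjusted p = 0.000489), after cyclic loess (0.0368), after quantile normalization (0.0261) and without TCR-positive CD44hi replicate 2 (0.0440). T helper lineage genes were higher with a TCR (9 of 17) and without (8 of 17), among them Ahr by 3.79 and 2.99, Rora by 2.74 and 2.96, Tbx21 by 2.98 and 2.65 and Ifng by 3.40 and 2.80. Tbx21 and Ifng were below the lower quartile of every array in CD62Lhi cells, so their differences are best read as lower bounds. The list was called with a TCR (camera adjusted p = 7.90e-10; adjusted p = 0.00455 with an estimated correlation) and without (camera adjusted p = 1.40e-07; adjusted p = 0.00528 with an estimated correlation).

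Interferon response genes were lower in CD44hi cells, 9 of 15 with a TCR, 2 higher, and 8 of 15 without, 1 higher, with Usp18 at -1.39 and -1.34 and Oasl2 at -1.16 and -0.89; the list calls (camera adjusted p = 0.0136 and 0.00796) were lost with an estimated correlation (adjusted p = 0.118 and 0.110). Of the TCR gamma genes, Trgv4 was lower in CD44hi cells by both of its brighter probe sets, at -2.27 and -2.46 with a TCR and -2.00 and -1.95 without. Trgv1 was also lower, at -1.285 with a TCR (limma adjusted p = 0.00285) and -1.185 without (limma adjusted p = 0.00612).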
